A study of Homo sapiens with 12 samples.

How the data were processed

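RNA from 12 samples of HCT-116, an established human colorectal carcinoma cell line, was measured with NanoString nCounter, a method that counts fluorescent barcodes on probes hybridised to single transcripts without amplification. Per the labels' protocols, cells were treated for 24 h with heteronemin, with tetrac or with both, total RNA was isolated with TRIzol, and the PanCancer Progression panel was used. The labels put 3 samples in each of 4 groups: control, heteronemin, tetrac and the combination. They do not say that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Doses are not given in the sources used here.

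Per the series' design text, the authors normalized the raw counts with nSolver 4.0, with a positive control factor for each sample and a further biological normalization. The values used here are 3 tables of the authors, 1 per treatment, each with 770 genes, of which 740 are endogenous and 30 housekeeping genes. The authors deposited a normalized signal, the group mean of normalized counts, for the treated group and for control. The control column was the same in all 3 tables. The lowest value of any group mean was 33, taken here as the authors' floor. The authors deposited a score that is a signed fold change, negative where the treated mean was lower; it matched the quotient of the deposited means within 0.00511. The authors deposited a p-value for each gene, printed to 2 decimals and empty where both means were at the floor. The test behind the p-value, the kind of mean and any threshold for background are not given in the sources used here. Values per sample were not analysed here, so no SD, interval or library depth can be given, and a p printed as 0 stands for any p below 0.005.

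From these tables, log2 ratios of the treated mean over the control mean were computed. A gene was called changed at the authors' unadjusted p under 0.05, the rule fixed for tables of ratios with p-values. Benjamini-Hochberg adjustment over the genes of each table was computed from the p-values as printed and, because of the rounding, also from the largest p that rounds to each printed one. The comparisons between treatments and the interaction had no test, since the tables hold none; genes at a fold of 1.5 or more were counted as a description. For 16 gene lists, Fisher's exact test (two-sided) compared called members with called genes outside the list, per direction, with Benjamini-Hochberg adjustment over all lists, directions and comparisons. The list median was ranked among 10000 random lists of equal size and, added after seeing the data, among random lists matched on level. Of 437 listed genes, 239 were measured.

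The named genes are the 10 largest rises and the 10 largest falls among called genes per comparison with control, up to 4 called members per list with the largest change, 20 genes chosen in advance, and the 5 largest differences in each direction between treatments. These rules, the lists, the tests and the first set of alternative settings were chosen before the data were examined. Of the 20 genes, CCND1, ITGAV, CD274 and PCNA are not analysed here. Some other genes that the rules name are not reported here. A planned minimum level of 20 counts removed 0 genes, since the floor lies above it. All settings that refer to a gene's level were added after seeing the data: a mean level of 100 or more over the 4 groups, which 356 genes reached, and a level correction, the log2 ratio minus the median of the 51 genes nearest in mean level. The mean level includes the treated values, so a gene at the floor in control reaches a higher level only by rising, and near the floor the correction takes off part of the rise itself. A gene's place was also given as its percentile among its 50 neighbours in level.

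Gene symbols are those of the tables; 755 of 770 were current symbols in the reference gene table, and the other 15 were older symbols matched by accession. The tables name no genome build, so no coordinates are given. The counting of calls was tested on simulated tables of 770 genes with 3 libraries per group and an assumed library SD of 0.15 on the log2 scale. In the simulation of a treated group against control, 84% of 150 genes changed 1.5-fold and 100% of 50 genes changed 2-fold were called in the right direction, and 3.85% of 156 unchanged genes were called. All these genes had a mean level of 100 or more, so the shares do not cover genes near the floor. The noise was independent between genes, without shifts of a whole library. The comparisons share the control libraries, so the correlation and overlap of unchanged groups were simulated too. That second simulation drew normal values of equal spread, without gene levels, a floor or rounding of p-values. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with figures from matplotlib 3.10.9.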

Results

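The panel measured 770 genes of tumour progression, among them genes of adhesion, extracellular matrix, angiogenesis and epithelial identity, in HCT-116 cells after 24 h. Heteronemin is a sesterterpenoid from a marine sponge, and tetrac is tetraiodothyroacetic acid, a deaminated analogue of thyroxine. The study's title asks whether they act against proliferation by blocking signalling through the EGF receptor. The panel counts transcripts, so neither receptor signalling nor proliferation was measured here. The sum of the authors' means over the panel was 333810 in control, 280484 after heteronemin, 306898 after tetrac and 297671 after the combination. These are normalized sums; the raw depth is unknown. In control, 279 genes were at the floor of 33, against 70 after heteronemin, 61 after tetrac and 90 after the combination. The housekeeping genes had a geometric mean of 299.6, 296.1, 299.5 and 297.5 in the same order.

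Heteronemin alone was set against control to ask which panel genes it changed. CXCL8, which encodes the neutrophil attractant interleukin-8, rose 8.16-fold, from the authors' mean of 65.5 to 535. JUN, a subunit of the AP-1 transcription factor, rose 3.51-fold, and SPP1, the secreted phosphoprotein osteopontin, rose 3.77-fold. The control mean of SPP1 was 36.35, near the floor of 33. The Notch ligand JAG1 fell from the authors' mean of 782 to 319, 2.45-fold lower, and the growth factor BMP4 fell from 3561 to 1549.8, 2.30-fold lower. In all, 191 of 704 tested genes passed in the authors' deposited table, 79 higher and 112 lower, where 35.2 would pass by chance. The balance depended on the size and level of the change: 64 rose and 31 fell at 1.5-fold or more, 38 and 5 at 2-fold or more, and 33 and 103 among genes at a mean level of 100 or more. Of the 30 housekeeping genes, 2 rose and 8 fell.

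Other large rises after heteronemin were RUNX1T1 (3.74-fold, from the floor in control), the hexokinase family member HKDC1 (3.34-fold), the semaphorin and VEGF co-receptor NRP1 (3.26-fold), MYCL (3.23-fold), the secreted phospholipase PLA2G2A (2.76-fold) and dermatopontin, DPT (2.73-fold). CKMT1A rose 2.70-fold, but its near-identical copy CKMT1B makes its identity uncertain. Large falls were seen in the lysosomal protease CTSH (2.21-fold lower), the inhibitor of differentiation ID2 (2.18-fold lower), the caveolar coat protein CAV1 (2.04-fold lower), RBL1, a relative of the retinoblastoma protein (1.76-fold lower), and the sodium channel subunit SCNN1A (1.74-fold lower). PTTG1, which encodes securin, was 1.68-fold lower, and the actin-severing protein GSN was 1.67-fold lower. Of the 10 largest rises, 6 lay at or above the 95th percentile of their neighbours in level, with HKDC1, MYCL, PLA2G2A and DPT at 94, 92, 88 and 84, and of the 10 largest falls, 9 lay at or below the 5th, with SCNN1A at 6. Near the floor, neighbours in level include genes placed there by their own rise.

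EGFR fell by 0.38 on the log2 scale after heteronemin, from the authors' mean of 502 to 385, with p = 0.04 in the authors' deposited table. Its percentile among the 50 genes of nearest level was 20. Of the 16 measured genes of the EGFR and ERBB list, 4 fell and 0 rose: the kinase ERK1, encoded by MAPK3 (1.72-fold lower, percentile 0 among its neighbours), PLCG1 (1.40-fold lower), EGFR, and STAT3 (1.28-fold lower). ERBB2 had a log2 ratio of 0.38 and ERBB3 of 0.35, neither of them called. In the PI3K and AKT list, 6 of 11 genes fell, among them AKT1 (1.45-fold lower), AKT2 (1.32-fold lower) and PIK3CA (log2 ratio -0.32); the list's adjusted p was 0.0800 by Fisher's exact test. After level correction 4 of the 6 kept their direction, MTOR and RPS6KB1 turned to 0.045 and 0.124, and the list median lay at percentile 32.0 of random lists matched on level. Adjusted over the list alone, 2 genes of the EGFR and ERBB list and 0 of the PI3K and AKT list passed, on the printed p-values and on the largest that rounding allows.

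Adhesion and matrix genes moved in both directions after heteronemin. Of 17 integrins, 5 fell, with ITGB4 at 1.60-fold, ITGA2 at 1.59-fold and ITGA1 at 1.40-fold lower, and ITGB8 at a log2 ratio of -0.58. Of 13 collagens, 3 rose: COL7A1 (2.17-fold), COL1A1 (2.15-fold) and COL5A2 (1.89-fold). They lay 0.46, 0.84 and 0.08 above the median of genes of like level. Of 10 laminin and basement membrane genes, 3 rose, among them the laminin chains LAMA3 (2.51-fold) and LAMB3 (2.12-fold). Of 24 matrix proteases and inhibitors, 3 rose and 4 fell: CTSK and ADAM17 rose by 0.72 and 0.40 on the log2 scale, while CTSH, MMP14, TIMP1 and ADAM9 had log2 ratios of -1.15, -0.60, -0.54 and -0.48. MMP9, at the floor in control, had a log2 ratio of 1.14 and was not called. Adjusted over the list alone, 2 integrins, 1 collagen, 3 laminin genes and 2 protease genes passed on the printed p-values, and 2, 0, 3 and 0 on the largest p that rounding allows.

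Among 26 angiogenic genes, NRP1, ANGPTL4 (2.16-fold), THBS1 (1.49-fold) and PDGFA (1.37-fold) rose and JAG1 fell, and VEGFA had a log2 ratio of 0.52 without being called. Of 16 hypoxia genes, 4 rose, among them the haem oxygenase HMOX1 (2.14-fold) and NDRG1 (log2 ratio 0.59), and 4 fell, among them the glycolytic enzymes LDHA (1.52-fold lower) and PGK1 (1.49-fold lower). HIF1A fell by 0.36 on the log2 scale, but lay 0.05 above the median of genes of like level. In the stress list of 7 genes, JUN, HMOX1 and NR4A3 (1.58-fold) rose. Of 14 inflammatory genes, CXCL8, the prostaglandin synthase PTGS2 (2.55-fold) and ICAM1 (1.54-fold) rose. After level correction, which takes off part of a rise near the floor, CXCL8 lay at 3.24, JUN at 1.95 and HMOX1 at 1.08. PTGS2 lay at 0.16, NR4A3 at 0.03 and ICAM1 at -0.39. The counts that passed adjusted over the list alone were 3 angiogenic, 1 hypoxia, 3 stress and 1 inflammatory genes on the printed p-values, and 3, 0, 1 and 0 on the largest p that rounding allows.

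Epithelial genes were split after heteronemin: of 24, 4 rose, led by KRT7 (2.46-fold) and CEACAM6 (2.45-fold), and 4 fell, among them the membrane protease ST14 (1.55-fold lower) and E-cadherin, CDH1 (1.36-fold lower). Of 21 mesenchymal genes, SPP1, ZEB1 (2.42-fold), SNAI1 (2.31-fold) and LOXL2 (1.99-fold) rose and FN1 fell to the floor (1.41-fold lower). VIM had a log2 ratio of -0.14 and was not called. Above the median of genes of like level, ZEB1 and KRT7 lay only 0.03 and 0.04, LOXL2 0.34, CEACAM6 0.48, SPP1 1.29 and SNAI1 1.35. Near the floor, that median takes in part of the rise itself. Of 21 TGF-beta and BMP genes, 7 fell, led by BMP4, ID2, ID1 (1.60-fold lower) and BMPR2 (1.51-fold lower). In the WNT list, CTNNB1, which encodes beta-catenin, fell 1.46-fold, as 1 of 8 genes, and MYC had a log2 ratio of -0.07. Of 9 cell cycle genes, 4 fell, among them CDKN1A (1.37-fold lower), CDC42 (1.34-fold lower) and RB1 (1.27-fold lower). After level correction, CTNNB1, CDKN1A, CDC42 and RB1 lay at -0.12, -0.09, 0 and -0.02, close to genes of like level. Of 14 markers of endothelial, blood and stromal cells, CD34 rose 2.38-fold. Adjusted over the list alone, 0 epithelial, 2 mesenchymal, 1 TGF-beta and BMP, 0 WNT, 0 cell cycle and 0 other-cell genes passed on the printed p-values; on the largest p that rounding allows, the TGF-beta and BMP count was 0 and the mesenchymal count 2. TGFB1 had a log2 ratio of -0.15, ITGB3 of 0.72 from the floor, and TGFBI was at the floor in all 4 groups.

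After Benjamini-Hochberg adjustment of the printed p-values, 41 genes passed for heteronemin in the authors' deposited table; with the largest p that rounding allows, 0 passed, at a smallest adjusted p of 0.0859. The median log2 ratio was -0.39 for the 84 genes at a mean level of 800 or more. It was 1.14 for the 95 genes at a mean level from 50 to under 75, a level that includes the treated values.

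**Figure D1:**
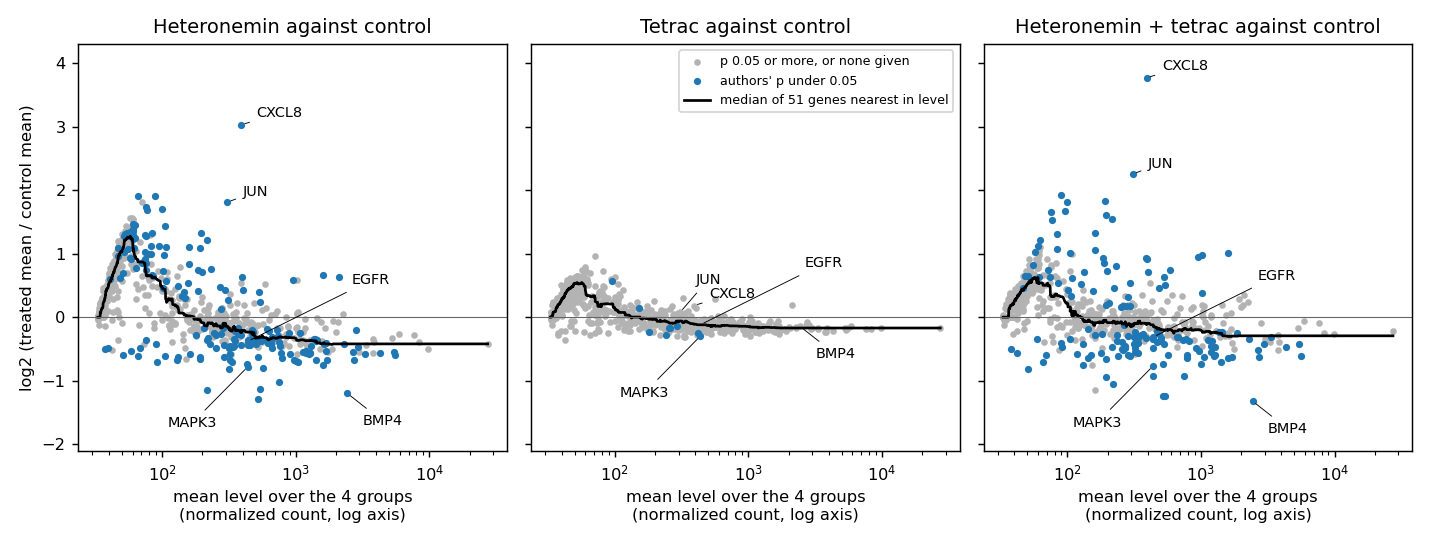
Log2 ratio of the treated over the control mean (vertical axis) against the mean level over the 4 groups (horizontal log axis, normalized counts), 1 point per gene and 1 panel per treatment, with genes past the authors' p in blue. The running median (line) lies below 0 at high levels in all 3 panels; near the floor it lies above 0, where the mean level includes the treated values and so the rise itself. EGFR lies near the line, while CXCL8, JUN, BMP4 and MAPK3 lie away from it after heteronemin with and without tetrac.

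Tetrac alone was set against control with the same question. The largest change among called genes was a rise of ANGPTL4, a secreted inhibitor of lipoprotein lipase, from the authors' mean of 48.6 to 71.8, or 1.48-fold. The other called rise was that of the ephrin receptor EPHA1 (1.11-fold). MAPK3 fell 1.23-fold, the glucose transporter SLC2A1 1.21-fold, the urokinase gene PLAU 1.19-fold and the angiogenic factor AGGF1 1.17-fold. The tight junction gene OCLN was 1.13-fold lower, DPYSL3 was 1.12-fold lower and the laminin chain LAMA5 was 1.10-fold lower. In the authors' deposited table, 9 of 714 tested genes passed at the unadjusted p, 2 higher and 7 lower, where 35.7 would pass if p-values were evenly spread. They were not, as 212 genes at the floor in control had a printed p of 0.42, so the shortfall does not measure a lack of effect. After Benjamini-Hochberg adjustment 0 passed, at a smallest adjusted p of 0.657 with the largest p that rounding allows.

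The fixed genes were not called after tetrac. EGFR had a log2 ratio of -0.12, with the authors' mean at 462 and p = 0.29 in the authors' deposited table, ERBB2 of 0.43, ERBB3 of -0.07, HIF1A of -0.06 and VEGFA of 0.02. The log2 ratio was -0.12 for CTNNB1, -0.17 for MYC, 0.46 for MMP9, 0.11 for THBS1, -0.06 for TGFB1, 0.43 for ITGB3, -0.10 for CDH1, -0.24 for VIM and -0.22 for CDKN1A. By list, called genes were lower for MAPK3 among EGFR and ERBB genes, LAMA5 among laminin genes, PLAU among proteases, SLC2A1 among hypoxia genes and OCLN among epithelial genes, and higher for ANGPTL4 among angiogenic and hypoxia genes. In the other 10 lists, 0 genes were called, and adjusted over the list alone 0 genes passed in any of the 16 lists. Of the 223 genes at the floor in control and above it after tetrac, 212 had a printed p of 0.42 in the authors' deposited table.

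The combination was set against control to ask what both compounds changed together. CXCL8 rose 13.6-fold, to the authors' mean of 892, and JUN rose 4.77-fold, to 569. SPP1 rose 3.77-fold, from near the floor, and the laminin chain LAMB3 rose 3.57-fold, from the authors' mean of 102 to 363. BMP4 fell 2.50-fold, to the authors' mean of 1423, ID2 fell 2.37-fold and JAG1 fell 2.36-fold. In the authors' deposited table, 153 of 686 tested genes passed, 56 higher and 97 lower. If p-values were evenly spread, 34.3 would pass, but this too is only a rough guide. Of 195 genes at the floor in control and above it after the combination, 148 had a p of 0.42. At 1.5-fold or more, 38 rose and 31 fell, and at a mean level of 100 or more 38 rose and 89 fell.

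Further rises under the combination were those of NRP1 (3.52-fold), ANGPTL4 (3.19-fold), HKDC1 (3.16-fold), POPDC3 (3.04-fold), SNAI1, a repressor of E-cadherin transcription (2.93-fold), and MYCL (2.88-fold). Those of NRP1, HKDC1 and MYCL started near the floor. CTSH fell 2.07-fold, RGCC 1.93-fold, CAV1 1.91-fold, GSN 1.90-fold, BMPR2 1.77-fold, MAPK3 1.71-fold and the endothelial junction gene JCAD, listed as KIAA1462, 1.69-fold. EGFR fell by 0.31 on the log2 scale to the authors' mean of 404, with p = 0.01 in the authors' deposited table and a percentile of 22 among genes of like level. Besides EGFR and MAPK3, PLCG1 fell (1.33-fold lower), as 3 of 16 EGFR and ERBB genes, against 94 of 670 tested genes outside the list. ERBB2 had a log2 ratio of -0.01 and ERBB3 of -0.40.

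The TGF-beta and BMP list stood out in the combination: 9 of its 19 tested genes fell and 0 rose, against 88 of 667 tested genes outside the list that fell (adjusted p = 0.0416, Fisher's exact test over 96 list tests). With BMP4, ID2 and BMPR2, the fourth largest fall was that of ID1 (1.55-fold lower), and TGFB1 fell 1.31-fold. Its median log2 ratio was -0.16, at percentile 0.57 among 10000 random lists of equal size. It was the only list to pass in any comparison. After heteronemin alone, 7 of its 20 tested genes fell and 0 rose (adjusted p = 0.378, Fisher's exact test), and the difference from the combination was not tested. The list test lost its call among genes at a level of 100 or more, where the smallest adjusted p was 0.322, and with members counted only at 1.5-fold, where it was 0.0768. Adjusted over the list alone, 8 genes passed in the combination on the printed p-values, or 4 on the largest that rounding allows. Fisher's exact test took the genes as independent, which members of 1 pathway measured in the same samples need not be.

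Of 10 laminin and basement membrane genes, 4 rose under the combination, among them LAMB3, LAMA3 (2.48-fold) and LAMA5 (1.12-fold), at an adjusted p of 0.06997. Of 7 stress genes, JUN, HMOX1 (2.50-fold), the stress cytokine GDF15 (1.98-fold) and NR4A3 (1.46-fold) rose, at an adjusted p of 0.0559. Of 26 angiogenic genes, 6 rose and JAG1 fell; the risers included NRP1, ANGPTL4 and VEGFA, which rose 1.67-fold to the authors' mean of 771. Of 16 hypoxia genes, 5 rose, among them NDRG1 (1.93-fold) and HMOX1, and LDHA fell (1.53-fold lower). When adjusted over the list alone, 4 laminin, 4 stress, 5 angiogenic and 6 hypoxia genes passed on the printed p-values, and 4, 4, 3 and 5 on the largest p that rounding allows.

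Of 24 proteases and inhibitors, 4 rose, among them CTSL (1.91-fold), ADAM17 (1.55-fold) and PLAUR (1.44-fold), and CTSH and MMP14 (1.27-fold lower) fell. COL7A1 rose 2.10-fold, while COL18A1, COL6A1 and COL6A2 were 1.52-fold, 1.38-fold and 1.08-fold lower. Of the integrins, ITGB4 fell 1.67-fold and ITGA2 1.32-fold, and of the PI3K and AKT genes PIK3R2 and AKT1 fell, each 1.37-fold. KRT7 (1.78-fold) and CLDN7 (1.31-fold) rose among epithelial genes, while ST14, TJP3 and AP1M2 were 1.56-fold, 1.43-fold and 1.40-fold lower; CDH1, at a log2 ratio of -0.11, was not called. SPP1, SNAI1 and ZEB1 (2.04-fold) rose and FN1 fell (1.41-fold lower) among mesenchymal genes. CTNNB1 (1.43-fold lower, at -0.22 after level correction) and CD44 (1.19-fold lower, but at 0.04 after level correction) fell in the WNT list. In the cell cycle list 3 genes fell, among them RB1 (log2 ratio -0.38) and CDC42 (1.27-fold lower), at -0.18 and -0.05 after level correction. CXCL8 was the 1 called inflammatory gene, and 0 of 14 markers of other cell types were called. Adjusted over the list alone, 5 protease, 0 collagen, 1 integrin, 0 PI3K and AKT, 1 epithelial, 2 mesenchymal, 0 WNT, 3 cell cycle, 1 EGFR and ERBB, 1 inflammatory and 0 other-cell genes passed on the printed p-values. On the largest p that rounding allows, 2 mesenchymal and 3 cell cycle genes passed, and 0 genes of these other 9 lists.

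Of the fixed genes not named above, THBS1 rose 1.53-fold under the combination. HIF1A had a log2 ratio of -0.10, MYC of 0.18, MMP9 of 0.23, ITGB3 of 0.43, VIM of 0.10 and CDKN1A of -0.22, none of them called. Benjamini-Hochberg adjustment of the printed p-values left 48 genes in the authors' deposited table, and 0 with the largest p that rounding allows, at a smallest adjusted p of 0.0715.

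**Figure D2:**
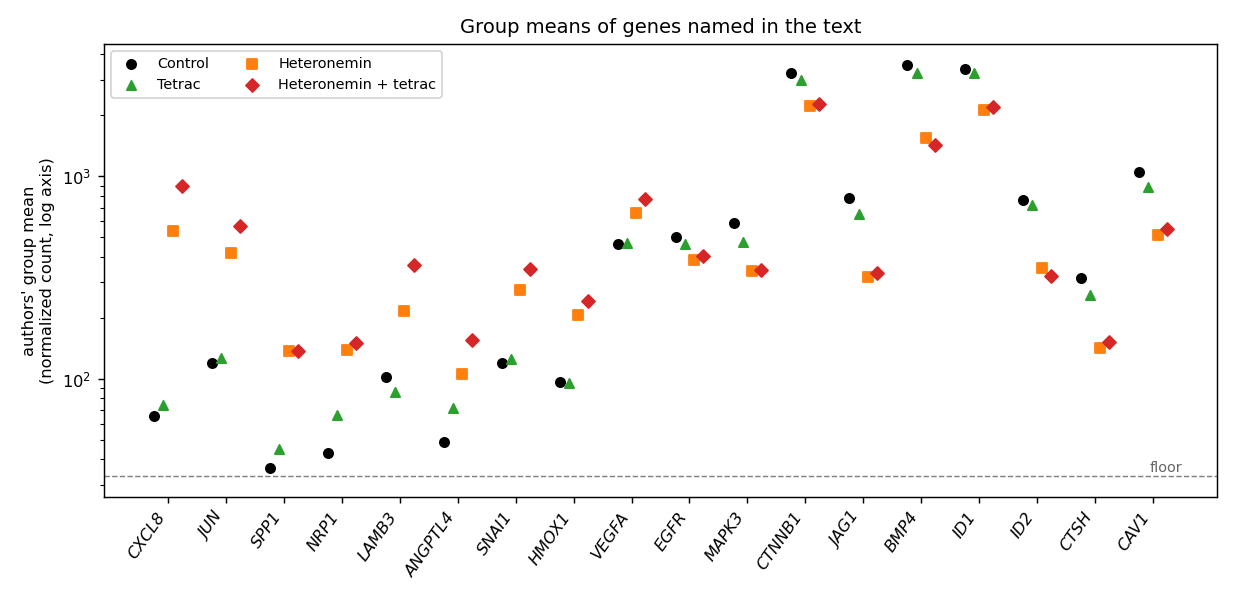
The authors' mean of normalized counts (vertical log axis) for 18 named genes (horizontal axis), 1 symbol per group; the tables give no spread for these means. CXCL8 reaches 535 after heteronemin and 892 after the combination, from 65.5 in control, and BMP4, ID1 and ID2 are lower in both groups that received heteronemin.

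The treatments were then compared over genes. Heteronemin and the combination shared 110 called genes, all in the same direction, 39 higher and 71 lower. Independent lists would share 6.51 and 16.0, and unchanged groups against the same controls shared 3.86 genes in simulation. ANGPTL4, DPYSL3 and MAPK3 were called in all 3 comparisons, in the same direction. SLC2A1 was also called after both heteronemin and tetrac, AGGF1 after both tetrac and the combination, and LAMA5 fell after tetrac and rose under the combination. The log2 ratios over all 770 genes, which are not independent replicates, had a Pearson correlation of 0.869 between heteronemin and the combination, 0.834 between heteronemin and tetrac and 0.623 between tetrac and the combination. Unchanged groups of equal spread sharing the controls gave 0.4999 in simulation. At a level of 100 or more and after level correction, the correlation was 0.908 and 0.851 for heteronemin and the combination. It was 0.583 and 0.558 for heteronemin and tetrac, and 0.349 and 0.394 for tetrac and the combination. The values for tetrac and the combination lie below 0.4999, but groups of unequal spread can give less than that without any change, so this decides nothing. The covariances were 0.235, 0.131 and 0.0743 over all genes, where the shared controls add 0.0183, 0.0183 and 0.0190 as estimated from the p-values. At a level of 100 or more they were 0.193, 0.0334 and 0.0215, where the controls add 0.00767, 0.00767 and 0.00934. The estimate assumes equal spread in treated and control samples, which fails for genes at the floor in control. The controls could not be split, as only their mean was used.

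Heteronemin against control and the combination against tetrac have no library in common. CXCL8 was 11.99-fold, JUN 4.52-fold, LAMB3 4.21-fold, SPP1 3.06-fold and SNAI1 2.80-fold higher in the combination than in tetrac. BMP4 was 2.26-fold, ID2 2.24-fold, ITGB8 2.15-fold and RGCC 1.89-fold lower, and JAG1 had a log2 ratio of -0.97. Of the genes called after heteronemin, 73 of the 79 higher and 103 of the 112 lower had the same direction between the combination and tetrac. After level correction of the latter comparison, 64 and 94 did. Of the 10 largest rises after heteronemin, 9 kept their direction, and RUNX1T1, at a log2 ratio of -0.03, did not. The Pearson correlation was 0.491 over all 770 genes and 0.798 over the 356 genes at a level of 100 or more. By Spearman it was 0.421 and 0.677. At 1.5-fold, 37 genes were higher and 13 lower in the combination than in tetrac, with no test.

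**Figure D3:**
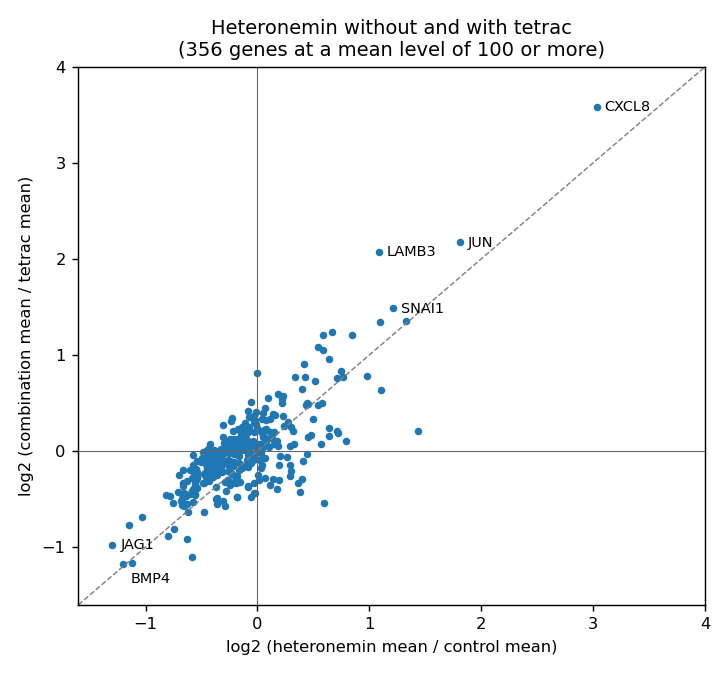
Log2 ratio of combination over tetrac (vertical axis) against that of heteronemin over control (horizontal axis), for the 356 genes at a mean level of 100 or more, 1 point per gene; the dashed line marks equal ratios. The Pearson correlation is 0.798, with CXCL8, JUN, LAMB3 and SNAI1 high on both axes and BMP4 and JAG1 low on both.

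Heteronemin was set against tetrac without a test. CXCL8 was 7.19-fold, JUN 3.33-fold, SPP1 3.05-fold, HKDC1 2.64-fold and LAMB3 2.50-fold higher after heteronemin. SCNN1A was 2.14-fold, BMP4 2.08-fold, ID2 2.06-fold, JAG1 2.04-fold and CTSH 1.83-fold lower. At 1.5-fold, 112 genes were higher and 13 lower, and 91 of the higher genes had a mean level under 100. After level correction, which takes off part of a rise near the floor, 25 were higher and 27 lower.

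The combination was set against heteronemin to ask what tetrac added. LAMB3 was 1.69-fold and CXCL8 1.67-fold higher in the combination, CBLC 1.48-fold, ANGPTL4 1.47-fold and the ephrin receptor EPHA2 1.46-fold. RUNX1T1 was 2.37-fold, TPSB2 2.04-fold, MAF 2.03-fold, PIK3R6 1.91-fold and FGL2 1.89-fold lower, each at the floor in control. At 1.5-fold, 2 genes were higher and 74 lower, of which 72 lay at a mean level under 100; at 100 or more, 4 genes reached that fold. With the same correction, 8 were higher and 4 lower. None of these differences was tested.

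The interaction, the log2 ratio of the combination minus the sum of the single ratios, was highest for LAMB3 (0.99), EPHA2 (0.82), CBLC (0.66), NDRG1 (0.62) and PPFIBP2 (0.60). It was lowest for RUNX1T1 (-1.93), CXCR2 (-1.85), TPSB2 (-1.68), MAF (-1.64) and S100A7 (-1.44). In control, CXCR2 had a mean of 33.89 and the others were at the floor of 33, so these values rest on bounds. At 1.5-fold, 5 genes lay above the sum and 223 below it, 217 of the latter at a mean level under 100, with no test. With the same correction, 31 lay above and 10 below, and at a level of 100 or more 9 genes reached that fold.

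**Figure D4:**
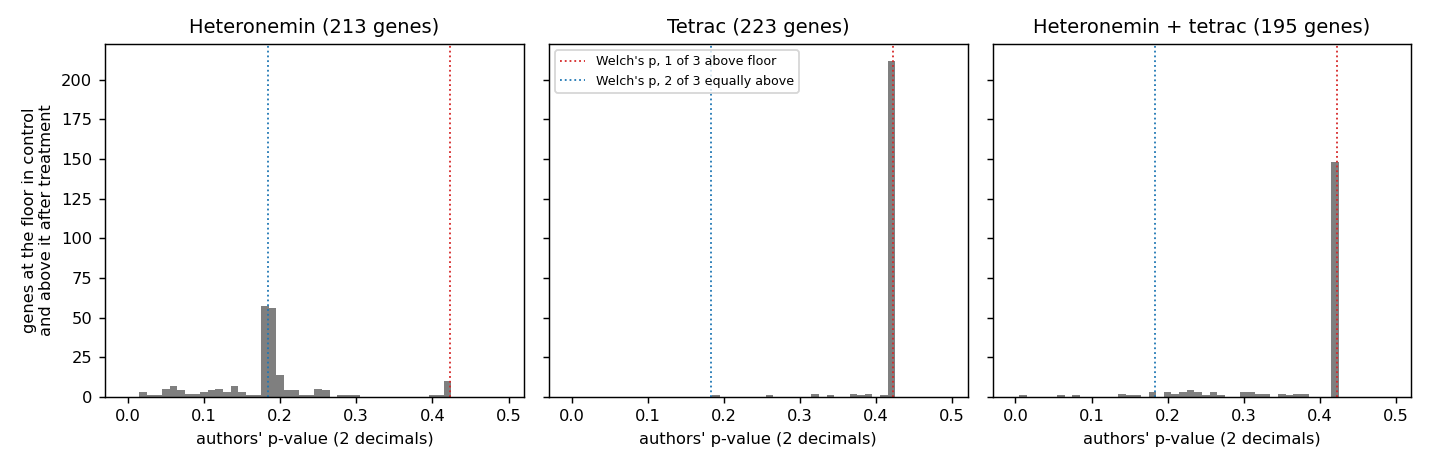
Number of genes (vertical axis) by the p-value in the authors' deposited table (horizontal axis) for genes at the floor in control and above it after each treatment, 1 panel per treatment. After tetrac, 212 of 223 genes lie at 0.42 (red dotted line, the value for a single library above the floor); after the combination, 148 of 195 lie there too, and after heteronemin, 127 of 213 lie at 0.18 to 0.20 (blue dotted line, the value for a pair of libraries equally above it).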

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

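Settings that use a gene's level, the largest p that rounding allows and a printed p of 0.05 or less were chosen after seeing the data. No paired analysis was possible because the tables hold group means only; for the same reason the replicate block, leaving out replicates, DESeq2 and other pseudocounts were not run. The planned minimum level of 20 changed nothing, as it removed 0 genes. Centring on the median of all or of the housekeeping genes kept the direction of all 191, 9 and 153 calls after heteronemin, tetrac and the combination. Benjamini-Hochberg adjustment left 41, 0 and 48 genes on the printed p-values and 0, 0 and 0 on the largest p; a fold of 1.5 left 95, 0 and 69, and a fold of 2 left 43, 0 and 23, since each asks more of a gene. The level correction kept the direction of 163, 9 and 150 calls; among called list members it turned HIF1A to 0.047, ICAM1 to -0.394, MTOR to 0.045, RPS6KB1 to 0.124 and SMAD4 to 0.139 after heteronemin, and CD44 to 0.044 after the combination, the cause not being tested. Near the floor, as for ICAM1, the correction takes off part of the rise itself, since the mean level includes the treated values, and decides nothing about a call. Combination against heteronemin, combination against tetrac, heteronemin against tetrac and interaction had 76, 50, 125 and 228 genes at 1.5-fold, 232, 155, 311 and 399 at the lower of the other fold minimums tried, and 3, 19, 18 and 81 at 2-fold. After centring on all genes, the split of heteronemin against tetrac was 77 higher and 19 lower. After level correction there were 12 (8 higher, 4 lower), 51, 52 (25 and 27) and 41 (31 and 10), and at a level of 100 or more, where fewer genes enter, 4, 35, 33 and 9. The correlation of heteronemin and tetrac was 0.797 over called genes, 0.583 at a level of 100 or more and 0.558 after level correction. That of heteronemin and the combination was 0.903 by Spearman, 0.919 over called genes and 0.908 at a level of 100 or more. That of tetrac and the combination was 0.727 by Spearman, 0.349 at a level of 100 or more and 0.394 after level correction. The 1 list call became 0 with members at 1.5-fold and 0 at a level of 100 or more; the cause of these shifts was not tested. The raw depth is unknown, and genes near the floor of 33 have only a bound.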

Other observations

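All tests in this part were chosen after the result was seen.

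In control HCT-116 cells, more epithelial than mesenchymal genes stood well above the floor. Of 24 epithelial genes, 16 had an authors' mean of 100 or more in control, with EPCAM at 1814, ESRP1 at 1712, KRT19 at 1604 and CLDN4 at 1001. Of 21 mesenchymal genes, 13 were at the floor in control, and CDH2, ZEB2 and LOX were at the floor in all 4 groups. Genes outside the lists, named after their values were seen, rose in both groups that received heteronemin: the adrenomedullin relative ADM2 by 0.98 and 1.02 on the log2 scale, the chaperone CLU by 0.67 and 1.01, and the tryptophanyl-tRNA synthetase WARS1, listed as WARS, by 0.64 and 0.92.

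Genes at the floor in control were above it after each treatment, 213 after heteronemin, 223 after tetrac and 195 after the combination, of 279. Of those 223, 95.1% had p = 0.42 in the authors' deposited table, as had 75.9% of the 195. Welch's test gives that p when 1 of 3 libraries lies above the floor and all controls at it, and induction in all 3 tetrac libraries would keep the same share, 95.1%, under 10%, so the tables argue against it. After heteronemin, 59.6% had a p of 0.18 to 0.20, as for 2 of 3 libraries about equally raised, so background in single libraries may account for much of the pattern. Induction by heteronemin stays open for all 213 genes, since neither a p in that range nor a missing call excludes it. The 5 called genes of this kind were CADM1, HAS1, PCOLCE, RUNX1T1 and TBXA2R. Of these, only HAS1 was also called in the combination, at 45.2 against 37.6 after tetrac. RUNX1T1, CADM1 and PCOLCE had authors' means of 52.2, 50.4 and 46.5 in the combination, against 53.3, 49.2 and 47.5 after tetrac. The test the authors used is not given in the sources used here.

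For genes at a level of 800 or more, the median log2 ratio was -0.39 after heteronemin, -0.16 after tetrac and -0.25 after the combination, though 0 of these 84 genes were called after tetrac. The tetrac libraries received no heteronemin, so their median, with an upper quartile of -0.13, argues against heteronemin as the only source. However, 1 library may have drawn the tetrac mean, and the tetrac and heteronemin ratios share the control mean. Over the 30 housekeeping genes, the Spearman correlation of log2 ratio and level was -0.50 after heteronemin, -0.49 after tetrac and -0.47 after the combination (permutation test, adjusted p = 0.00924, 0.00924 and 0.00993). Without the 2 genes farthest in level it was -0.651 after heteronemin. Scaling to housekeeping genes whose low members were raised would give that sign and may contribute. A real loss of abundant transcripts would give the same sign, so the correlation cannot tell them apart. The percentile of EGFR among genes of like level was 20 after heteronemin and 22 after the combination, within the range of its neighbours, while MAPK3 lay at 0 and 2. A real loss of abundant transcripts stays open and was not tested. All these medians and correlations rest on ratios with the same control mean as denominator, so they are not separate findings. A part of the control libraries in the trend after each treatment also stays open and was not tested.

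Heteronemin changes recurred between libraries not shared. The correlation was 0.49 over all genes and 0.80 at a level of 100 or more, which argues against chance values of the control libraries, and at that level 0.85 after level correction, which argues against the level trend. An effect of heteronemin on these genes is a hypothesis, found and tested on the same data. The same comparison for tetrac gave -0.71 over all genes, -0.46 at a level of 100 or more and, at that level after correction, -0.29. A value under 0 had been set as the bound against a tetrac effect that adds to that of heteronemin, but that bound made no allowance for a tetrac mean drawn by 1 library, an allowance added only once the value was known; with 37.4% of the tetrac p-values at that level between 0.30 and 0.50, against 10.7% after heteronemin, the additive effect stays undecided.

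Other splits of the samples could not be counted, since values per sample were not analysed here. Of 11 markers of other cell types at the floor in control, 9, 10 and 9 were above it after heteronemin, tetrac and the combination, against 76.1%, 79.5% and 69.4% of the other genes at the floor.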
